A study of Drosophila melanogaster with 80 samples.

How the data were processed

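Whole adult Oregon R flies were measured on 80 Affymetrix Drosophila Genome 2.0 arrays, in 20 groups of 4. Groups were defined by generation (F0, F1 or F2), sex, the diet of the flies themselves and, in F1 and F2, the diet of the F0 males they descend from. Per the labels, flies were virgin or unmated, lived on CD or HSD for 14 days at 25 °C, and 250 ng of RNA was amplified from the 3' end and labelled with biotin. The labels do not say whether the 4 arrays of a group came from separate vials, or what the F1 parents of the F2 flies ate. If they did not, p values measure only the spread between these samples, which may be technical.

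The deposited values are log2 signals per probe set, which the authors made with RMA, a method that subtracts background, normalizes arrays and summarizes probes; they also named limma, and gave no versions. Values ran from 2.33 to 14.76. Each array carries a batch label: 1 for F0, and 1 for each combination of sex and own diet within F1 and within F2. Within a set the sorted values of the 8 arrays differed by a median of 0.04 to 0.11 log2 units, against 1.15 over all 80 arrays, so each batch, and each sex within the F0 batch, was a separately normalized set. Comparisons of ancestry therefore lie within a set, and those of own diet in F1 and F2 do not. Arrays have no counts, and the number of arrays limits the precision.

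The table held 18952 probe sets. Left out were 183 controls, 402 probe sets with several gene symbols and 4720 with none, and 13647 with 1 symbol remained, for 11982 genes. Of these genes 1094 had more than 1 probe set, and the one with the highest mean over the 80 arrays was used. Symbols were checked against an Entrez-keyed annotation table, which matched 13544 probe sets and updated 0. Genes without a named probe set, Thor, Ilp6, roX1 and roX2 among them, were not analysed here.

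Each comparison was fitted with limma (lmFit, contrasts.fit and eBayes with default settings, two-sided) on the arrays of the groups compared. Genes with a mean under the 25th percentile of all probe sets in every group of the fit were left out. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were diet in F0 males and in F0 females, ancestry in each of the 8 descendant sets, the mean of both ancestry changes per generation and sex with own diet as a term, the difference between them, the difference between sexes in F0, and own diet in F1 and F2. Batch could enter as a term only in the averaged comparisons.

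34 gene lists of pathways, tissues and cell types were tested with limma camera, with a preset correlation of 0.01 between genes and with an estimated one, adjusted over the lists of a comparison, where at least 5 members were measured. Correlations between the changes of different comparisons were tested by regrouping the arrays of each set. Each count was also set against other splits of the same arrays, all 35 for 8 arrays and 100 drawn for 16. Sex-limited genes were those at least 5 log2 units apart between CD F0 males and females.

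Named genes followed a rule. In F0 these were the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap, and up to 4 members of each list called. In ancestry comparisons they were 5 and 5 with up to 3 members per list, or the 3 smallest p where none passed. Averaged comparisons and differences took 4 and 4, and up to 10 genes recurring across comparisons were added, as were genes of sugar and fat metabolism and of sex fixed in advance. The text names some of the 457 pairs of a gene and a comparison that qualified. In 41 pairs the gene had other probe sets, of which 19 had the opposite sign, and some of Obp19a, Su(var)2-10, rdgB, hdly, tim, Sh and Mlp60A changed over 1.5 times less or oppositely. Of all pairs 31 were read from probe sets that can match several transcripts. The comparisons, tests, lists, rule and most alternatives were chosen before the data were examined.

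Alternatives were no dim filter, a filter at the 50th percentile, a further quantile normalization, the mean of all probe sets, 1 fit of all 80 arrays, array weights, a trended robust variance prior, a replicate block, no batch term, each array left out in turn, Spearman in place of Pearson and an estimated correlation. Leaving out the arrays that hold opposite-sex transcripts, or genes limited to the other sex, was added after seeing the data.

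The fits were tested on simulated data, drawn from the mean and spread of each gene with changes added to 200 genes per comparison. In the F0 and 8 ancestry comparisons 12% to 84% of genes changed by 0.25 log2 units and 92% to 100% of those changed by 0.5 were recovered, with 3 to 18 false calls.

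R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table was used for fits, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for annotation and figures.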

Results

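Gene expression was measured in whole adult Oregon R flies, a laboratory wild-type strain of Drosophila melanogaster, on 80 Affymetrix Drosophila Genome 2.0 arrays. Flies were fed for 14 days on a control diet (CD, 0.15 M sucrose) or a high-sucrose diet (HSD, 1 M sucrose). The arrays formed 20 groups of 4: F0 males and females on each diet, and F1 and F2 males and females on each diet that descended from F0 males kept on CD or on HSD. The series asks whether the diet of F0 males leaves a trace in the expression of their F1 and F2 descendants. In descendants, ancestry below means the diet of the F0 males, and a change with ancestry is the log2 value in flies of HSD ancestry minus that in flies of CD ancestry fed the same diet. Array medians ran from 5.19 to 7.37 on the log2 scale, and the number of arrays limits the precision. Values are group means ± SD with n = 4 arrays, or log2 changes with their standard error (SE). For every gene named in a 2-group comparison all 4 arrays of 1 group lay beyond all 4 of the other, unless said otherwise.

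Sex-limited transcripts were set against the sex in the labels. The yolk protein gene Yp1 averaged 14.48 ± 0.15 in the 40 female arrays and 7.90 ± 1.61 in the 40 male arrays (SD, n = 40), and the male seminal fluid gene SP, which encodes sex peptide, averaged 4.33 ± 1.05 and 12.77 ± 0.25. The sperm gene Mst87F averaged 3.87 ± 0.61 in females and 12.21 ± 0.50 in males, and the testis tubulin betaTub85D 4.32 ± 1.00 and 11.99 ± 0.31. The mean of transcripts limited to the other sex (78 female-limited and 652 male-limited genes, at least 5 log2 units apart in F0 flies on CD) stood over 0.5 above the lowest array of its set in 6 arrays, all of HSD ancestry. These were F1 CD-fed males, replicates 1 (0.84) and 4 (0.76), F1 HSD-fed females, replicate 1 (0.73), and F2 HSD-fed males, replicates 1 (0.59), 2 (0.89) and 4 (0.70).

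Gene lists of pathways, tissues and cell types were tested with camera, which compares a list with all other genes. Of 334 pairs of a list and a within-batch comparison, 110 passed with the preset correlation between genes, and 0 did with an estimated correlation, where the smallest adjusted p was 0.0679 and 38 pairs had an unadjusted p under 0.05. In the comparisons averaged over diets, 53 of 135 pairs passed with the preset and 2 with an estimated correlation. The lists described here all passed with the preset correlation, their medians are of log2 changes, and none of the medians changed sign after quantile normalization.

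The F0 comparison in males asked how the flies that ate the high-sucrose diet themselves responded. The transcript of CG12374, a predicted digestive carboxypeptidase, rose from 7.60 ± 0.05 to 11.34 ± 0.20, a log2 change of 3.73 (SE 0.09, adjusted p = 1.34e-08), and the Jonah serine protease Jon99Fi by 2.49 (SE 0.26). The sugar-responsive transcription factor gene sug (sugarbabe) rose by 1.61 (SE 0.05, adjusted p = 7.13e-08). CG3999, which encodes the glycine dehydrogenase of the glycine cleavage system, fell from 10.19 ± 0.05 to 7.71 ± 0.05, a log2 change of -2.49 (SE 0.04, adjusted p = 7.01e-10), and the metallothionein gene MtnB had a log2 change of -2.37 (SE 0.07). The sterol-binding protein gene Npc2e (-2.50), the glutathione transferase gene GstD8 (-1.81) and CG34040 (-1.71) were also among the largest falls, and CG12057 (1.82), CG17192 (1.85) and the stress-induced Turandot gene TotC (2.58) among the largest rises.

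One-carbon and purine synthesis genes were lower in HSD-fed F0 males. Of 16 serine, methionine and folate metabolism genes 10 fell and 1 rose (11 lower and 1 higher adjusted over the list alone, median -0.41, adjusted p = 0.0679 by estimated correlation). Its members included Sardh (-1.46), Nmdmc (-1.43) and pug (-1.10), which encode sarcosine dehydrogenase and folate-interconverting enzymes. Of 15 purine and urate metabolism genes 11 fell and 2 rose (12 lower and 3 higher adjusted over the list alone, median -0.25, adjusted p = 0.0679 by estimated correlation), with the purine synthesis genes Gart (-1.56), Adsl (-1.25) and Prat2 (-1.17) among them. Of 21 sugar digestion and transport genes 14 fell and 2 rose (17 lower and 2 higher adjusted over the list alone, median -0.22, adjusted p = 0.153 by estimated correlation). Among these were the amylase-related gene Amyrel (-1.52) and the maltase genes Mal-A4 (-1.14), Mal-B1 (-1.14) and Mal-B2 (-1.02). Of 15 glycolysis and pentose phosphate genes 8 fell and 1 rose (8 lower and 1 higher adjusted over the list alone, median -0.13, adjusted p = 0.238 by estimated correlation), and the hexokinase gene Hex-C had a log2 change of -0.61 (SE 0.06). Of 91 detoxification genes 55 fell and 4 rose (63 lower and 7 higher adjusted over the list alone, median -0.24, adjusted p = 0.153 by estimated correlation).

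Immune lists were called as lower and the testis list as higher in HSD-fed F0 males. Of 21 antimicrobial and Bomanin peptide genes 12 fell and 1 rose (12 lower and 1 higher adjusted over the list alone, median -0.25, adjusted p = 0.238 by estimated correlation), with the defensin gene Def (-1.21) and the metchnikowin gene Mtk (-0.96) among them. Of 20 immune recognition and signalling genes 9 fell and 0 rose (9 lower and 1 higher adjusted over the list alone, median -0.10, adjusted p = 0.153 by estimated correlation), and pirk, an inhibitor of the Imd immune pathway, had a log2 change of -1.46 (SE 0.07). Of 36 testis genes 27 rose (28 higher adjusted over the list alone, median 0.23, adjusted p = 0.307 by estimated correlation), such as dj (0.39), which encodes a sperm tail protein. Of 40 proteasome genes 12 rose (12 higher adjusted over the list alone, median 0.08, adjusted p = 0.363 by estimated correlation). Among genes named in advance for their part in sugar and fat metabolism, the lipase gene bmm (-0.55), the sugar-responsive glucosidase gene tobi (-0.59), ACC (-0.19) and Mal-A1 (-0.15) were lower, and Pepck1 (0.31) and ImpL2 (0.30) higher. FASN1, the fatty acid synthase gene, did not pass, at 0.08 (SE 0.03, adjusted p = 0.102). With limma, 3358 of 10950 genes passed (2145 higher and 1213 lower).

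In F0 females Jon99Fi rose from 4.19 ± 0.33 to 11.81 ± 0.24, a CD mean near the lower limit of detection, with a log2 change of 7.61 (SE 0.17, adjusted p = 8.56e-09), and CG12374 from 7.97 ± 0.10 to 13.52 ± 0.10, a log2 change of 5.55 (SE 0.07, adjusted p = 1.86e-10). The Jonah protease genes Jon66Ci (3.88), Jon65Ai (3.71) and Jon65Aii (2.44) rose as well, beside CG12057 (4.88), CG5246 (3.23) and CG14820 (3.19). CG34040 fell from 11.26 ± 0.12 to 4.97 ± 0.73, a log2 change of -6.29 (SE 0.30, adjusted p = 7.50e-07), and Mal-A4 from 11.76 ± 0.11 to 7.06 ± 0.11, a log2 change of -4.70 (SE 0.07, adjusted p = 7.37e-10). Further large falls were those of Amyrel (-4.52), CG6283 (-4.42), CG8093 (-4.36), CG15533 (-4.22) and the lipase gene Lip3 (-3.75), whose HSD mean lay near the lower limit of detection. sug rose by 1.97 (SE 0.12).

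Of 19 sugar digestion and transport genes 16 fell and 2 rose (16 lower and 2 higher adjusted over the list alone, median -1.23, adjusted p = 0.352 by estimated correlation), including Mal-A3 (-3.30), tobi (-3.17) and Mal-A1 (-1.46). Of 29 midgut serine protease and lysozyme genes 6 fell and 18 rose (6 lower and 18 higher adjusted over the list alone, median 0.47, adjusted p = 0.492 by estimated correlation). Of 16 serine, methionine and folate metabolism genes 13 fell and 1 rose (13 lower and 1 higher adjusted over the list alone, median -0.51, adjusted p = 0.352 by estimated correlation), including Sardh (-2.52), CG3999 (-2.31) and pug (-2.30). Of 14 purine and urate metabolism genes 11 fell (11 lower adjusted over the list alone, median -0.42, adjusted p = 0.207 by estimated correlation), including Gart (-2.10) and the xanthine dehydrogenase gene ry (-1.24). Of 91 detoxification genes 55 fell and 4 rose (55 lower and 4 higher adjusted over the list alone, median -0.38, adjusted p = 0.422 by estimated correlation), with Cyp309a1 (-2.94) and GstD5 (-2.72) falling most, the latter to a mean near the lower limit. Of 18 fat body genes 9 fell and 2 rose (10 lower and 2 higher adjusted over the list alone, median -0.41, adjusted p = 0.571 by estimated correlation), and the storage protein gene Lsp2 had a log2 change of -3.44 (SE 0.12).

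Cell cycle genes were higher in HSD-fed F0 females. Of 22 DNA replication and cell cycle genes 20 rose (22 higher adjusted over the list alone, median 0.47, adjusted p = 0.492 by estimated correlation), such as Orc1 (0.69), aurB (0.68) and CycB3 (0.64), which act in replication origin firing and mitosis. Of 32 proteasome genes 25 rose (26 higher adjusted over the list alone, median 0.20, adjusted p = 0.352 by estimated correlation). Of 24 Polycomb and heterochromatin genes 1 fell and 19 rose (1 lower and 19 higher adjusted over the list alone, median 0.29, adjusted p = 0.492 by estimated correlation), with brm (0.40) and Su(var)2-10 (0.55) among the rises. Of 18 eggshell genes 6 rose (6 higher adjusted over the list alone, median 0.48, adjusted p = 0.713 by estimated correlation), including the vitelline membrane genes Vm26Ac (1.5) and Vm32E (1.5). Of 22 antimicrobial and Bomanin peptide genes 8 fell (8 lower adjusted over the list alone, median -0.28, adjusted p = 0.713 by estimated correlation). Of 21 immune recognition and signalling genes 10 fell and 3 rose (11 lower and 3 higher adjusted over the list alone, median -0.17, adjusted p = 0.492 by estimated correlation), with the peptidoglycan recognition genes PGRP-SB1 (-2.15) and PGRP-SC2 (-1.24) and pirk (-1.83) among the falls.

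The neuron and photoreceptor lists were called as higher in HSD-fed F0 females. Of 29 neuron genes 11 rose (11 higher adjusted over the list alone, median 0.22, adjusted p = 0.677 by estimated correlation). Of 18 photoreceptor genes 9 rose (9 higher adjusted over the list alone, median 0.30, adjusted p = 0.741 by estimated correlation). Among genes named in advance, Hex-C (-1.09), bmm (-0.58) and ACC (-0.42) were lower. FASN1 (0.07), ImpL2 (-0.07) and Pepck1 (-0.05) did not pass, and their groups overlapped. With limma, 4239 of 10251 genes passed (2369 higher and 1870 lower).

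**Figure D1:**
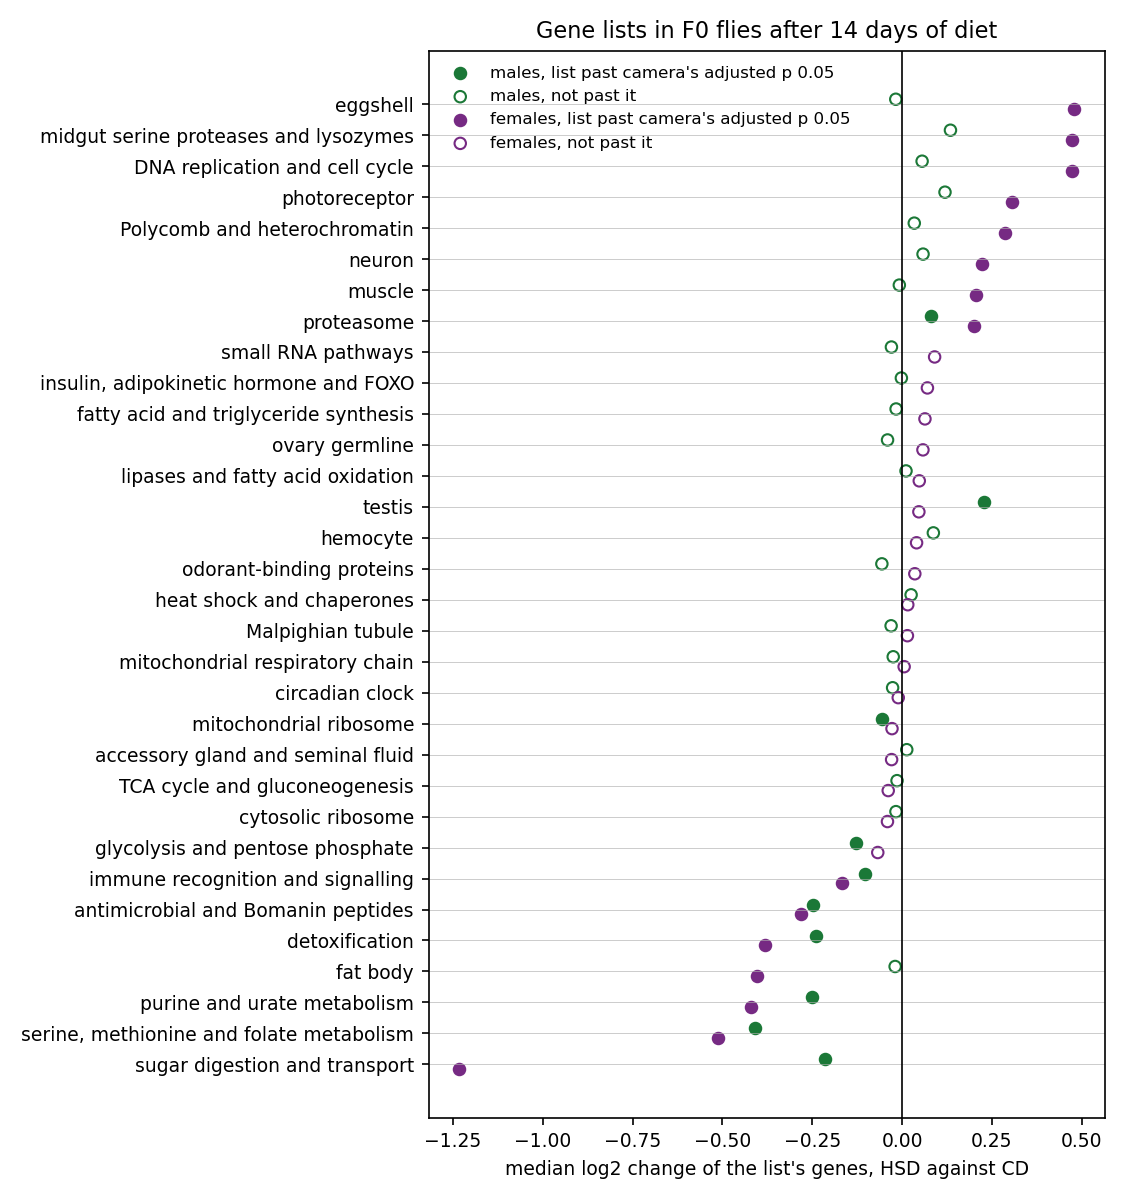
Points give the median log2 change (HSD minus CD, 4 arrays against 4) of each gene list's measured genes in F0 males (green) and F0 females (purple), filled where the list passed camera with the preset correlation. The sugar digestion and transport median is -0.22 in males and -1.23 in females.

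Males and females shared part of the F0 response and differed in its size. Of 9821 genes tested in both sexes 1428 passed in both, where independent lists of these sizes would share 1165. Of these, 511 were higher in both, 706 lower in both, and 211 changed in opposite directions. The test of the difference itself (female change minus male change) had 3445 of 11380 genes past the threshold, 1652 with the higher and 1793 with the lower value in females. The difference was 5.12 (SE 0.34) for Jon99Fi and 3.65 (SE 0.24) for Jon66Ci, the proteases that rose more in females, and the former rests on the low CD mean in females. It was -4.58 (SE 0.33) for CG34040 and -4.16 (SE 0.15) for CG31468, and CG31468 had a log2 change of -3.92 (SE 0.13) in F0 females, to a mean near the lower limit of detection.

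**Figure D2:**
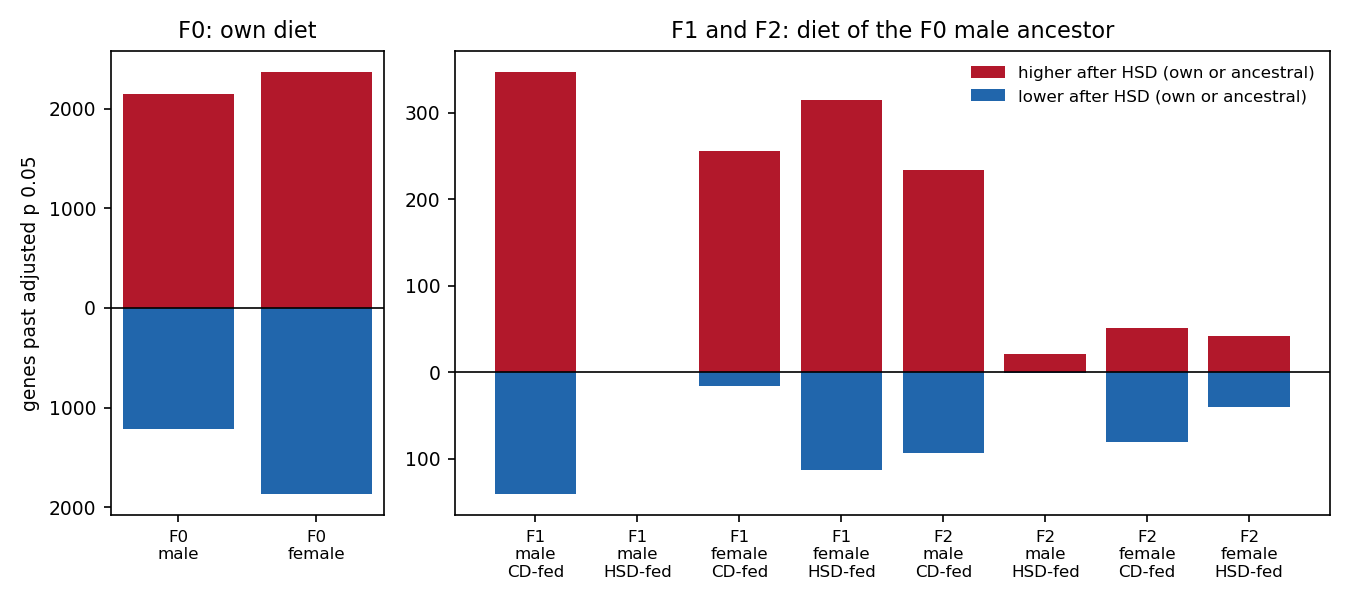
Bars give the number of genes past the adjusted p threshold of 0.05, upward for genes higher and downward for genes lower with HSD (F0, left axis) or HSD ancestry (F1 and F2, right axis, on its own scale). The F0 comparisons hold 3358 and 4239 genes and the ancestry comparisons 0 to 488.

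In F1 the comparisons asked whether sons and daughters of HSD-fed F0 males differed from those of CD-fed F0 males. Among CD-fed F1 males, GstD8 rose from 8.52 ± 0.04 to 9.11 ± 0.04 with HSD ancestry, a log2 change of 0.59 (SE 0.05, adjusted p = 2.47e-04), and the trypsin gene epsilonTry by 0.57 (SE 0.05, adjusted p = 2.47e-04). The odorant-binding protein gene Obp99b, which is expressed in fat body, rose by 0.55 (SE 0.05), and AANATL3, an acetyltransferase-like gene, by 0.67 (SE 0.07). TotC had the largest rise, 2.25 (SE 0.56, adjusted p = 0.0437), with SDs over 1 log2 unit in both groups. CG33337 (1.03), CG3819 (0.94) and phu (0.64) were further large rises, and CG8112 (-0.58), Acsx1L (-0.58) and the corneal lens gene retinin (-0.48) large falls.

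Of 89 detoxification genes 0 fell and 15 rose (1 lower and 29 higher adjusted over the list alone, median 0.12, adjusted p = 0.539 by estimated correlation). Of 18 fat body genes 4 rose (12 higher adjusted over the list alone, median 0.15, adjusted p = 0.506 by estimated correlation). Of 28 midgut serine protease and lysozyme genes 0 fell and 7 rose (2 lower and 9 higher adjusted over the list alone, median 0.10, adjusted p = 0.372 by estimated correlation), with kappaTry (0.49) and Jon99Ci (0.42) among the rises. Of 21 sugar digestion and transport genes 0 fell and 4 rose (1 lower and 11 higher adjusted over the list alone, median 0.16, adjusted p = 0.603 by estimated correlation), with Amyrel (0.34), tobi (0.23) and Mal-A6 (0.21) rising. Of 36 testis genes 2 fell (9 lower adjusted over the list alone, median -0.13, adjusted p = 0.583 by estimated correlation), including the sperm chromatin gene ProtA (-0.32). Of 13 eggshell genes 1 rose (2 higher adjusted over the list alone, median 0.10, 0.07 after quantile normalization, adjusted p = 0.372 by estimated correlation), namely Vm26Aa (0.33). The 2 arrays with more female-limited transcripts belonged to the HSD-ancestry group, whose female-limited mean was 5.35 ± 0.41, beside 4.92 ± 0.01 with CD ancestry.

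In CD-fed F1 males, 488 of 10800 genes passed (347 higher and 141 lower). After quantile normalization the split was 504 higher and 348 lower. In F1 CD-fed males, leaving out 1 array gave 154 to 566 genes, and the count moved by over 1.5 times without CD-ancestry replicates 1 (154), 3 (174) and 4 (301), HSD-ancestry replicates 1 (154) and 4 (179). The count was 955 with the 50th percentile dim filter, 852 with quantile normalization, 932 with 1 fit of all 80 arrays, 894 with array weights, 1213 with a trended robust variance prior and 60 with the arrays holding opposite-sex transcripts left out.

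In HSD-fed F1 males no gene passed with limma (0 of 10916), although 1274 had an unadjusted p under 0.05, and the smallest adjusted p was 0.113. The 3 genes with the smallest p were yellow-g (-0.71), LanA (-0.45) and phu (-0.39), and LanA encodes a laminin of the basement membrane. Of 17 hemocyte genes 0 fell (15 lower adjusted over the list alone, median -0.26, adjusted p = 0.585 by estimated correlation). This list holds markers of the blood cells of the fly. Of 71 mitochondrial respiratory chain genes 0 rose (3 higher adjusted over the list alone, median 0.07, adjusted p = 0.596 by estimated correlation). Simulations recovered 84% of genes changed by 0.25 log2 units and 98% at 0.5. They held larger changes too, so power for small changes alone was not measured. In F1 HSD-fed males, leaving out 1 array gave 0 to 2 genes (2 without CD-ancestry replicate 2). The count was 21 with the 50th percentile dim filter, 33 with 1 fit of all 80 arrays and 100 with a trended robust variance prior.

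In CD-fed F1 females odorant-binding protein genes of the antenna were among the genes with the largest rises. Obp19a rose from 5.33 ± 0.26 to 6.90 ± 0.34 with HSD ancestry, a log2 change of 1.57 (SE 0.17, adjusted p = 0.00313), and Obp83b from 6.05 ± 0.25 to 7.55 ± 0.34, a log2 change of 1.5 (SE 0.17, adjusted p = 0.00313). A second probe set of Obp19a changed by only 0.48. Os-C, another olfactory-segment gene, rose by 1.47 (SE 0.17) and Obp69a by 0.90 (SE 0.10). TotC rose by 2.52 (SE 0.38, adjusted p = 0.0111), and CG12057 by 1.03 (SE 0.15). The largest falls were those of the homeobox gene scro (-0.69), CG10505 (-0.54) and retinin (-0.44).

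Of 36 odorant-binding protein genes 10 rose (14 higher adjusted over the list alone, median 0.13, adjusted p = 0.279 by estimated correlation). Of 29 midgut serine protease and lysozyme genes 9 rose (23 higher adjusted over the list alone, median 0.28, adjusted p = 0.279 by estimated correlation), such as epsilonTry (0.85), Jon25Biii (0.68) and Jon99Ci (0.64). Of 91 detoxification genes 7 rose (14 higher adjusted over the list alone, median 0.08, adjusted p = 0.629 by estimated correlation). Of 19 sugar digestion and transport genes 0 fell and 2 rose (2 lower and 9 higher adjusted over the list alone, median 0.14, adjusted p = 0.633 by estimated correlation), with Mal-A4 (0.37) and Mal-A3 (0.33) rising. Of 17 lipase and fatty acid oxidation genes 2 rose (3 higher adjusted over the list alone, median 0.07, adjusted p = 0.629 by estimated correlation), with the lipase genes mag (0.63) and Lip3 (0.41) rising. Of 17 ovary germline genes 0 fell (1 lower adjusted over the list alone, median -0.11, adjusted p = 0.279 by estimated correlation). Of 16 hemocyte genes 0 rose (1 higher adjusted over the list alone, median 0.17, adjusted p = 0.633 by estimated correlation).

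In CD-fed F1 females, 271 of 10227 genes passed (255 higher and 16 lower). In F1 CD-fed females, leaving out 1 array gave 95 to 222 genes, with shifts over 1.5 times without CD-ancestry replicates 1 (98), 3 (180) and 4 (95), HSD-ancestry replicates 1 (176) and 3 (104). The count was 663 with 1 fit of all 80 arrays, 497 with array weights and 442 with a trended robust variance prior.

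In HSD-fed F1 females the heat shock gene Hsp68 fell from 9.85 ± 0.11 to 8.56 ± 0.30 with HSD ancestry, a log2 change of -1.29 (SE 0.14, adjusted p = 0.00450), and NimC4, a phagocytic receptor gene also called simu, had a log2 change of -0.99 (SE 0.12, adjusted p = 0.00702). pirk (-0.93), CG13026 (-1.16) and CG30098 (-0.94) were the other large falls. The metallothionein gene MtnC rose from 10.18 ± 0.04 to 11.04 ± 0.14, a log2 change of 0.87 (SE 0.07, adjusted p = 0.00260), and CG10621, a predicted homocysteine methyltransferase gene, by 0.69 (SE 0.09). CG9733 (1.07), CG16898 (1.06) and CG9701 (0.71) rose as well.

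Of 17 hemocyte genes 8 fell and 0 rose (12 lower and 1 higher adjusted over the list alone, median -0.33, adjusted p = 0.164 by estimated correlation), including the prophenoloxidase genes PPO1 (-0.56) and PPO2 (-0.52) and the phagocytic receptor gene eater (-0.46). Of 10 heat shock and chaperone genes 3 fell (5 lower adjusted over the list alone, median -0.08, adjusted p = 0.164 by estimated correlation), with DnaJ-1 (-0.31) and stv (-0.33) falling beside Hsp68. Of 68 mitochondrial respiratory chain genes 13 rose (27 higher adjusted over the list alone, median 0.08, adjusted p = 0.164 by estimated correlation), including SdhB (0.26). Of 17 TCA cycle and gluconeogenesis genes 5 rose (12 higher adjusted over the list alone, median 0.10, adjusted p = 0.164 by estimated correlation), with Pepck2 (0.61) and Ogdh (0.26) among them. Of 20 sugar digestion and transport genes 9 rose (11 higher adjusted over the list alone, median 0.15, adjusted p = 0.164 by estimated correlation), with Mal-A7 (0.43) among them. Of 18 photoreceptor genes 5 rose (10 higher adjusted over the list alone, median 0.13, adjusted p = 0.164 by estimated correlation), with ninaD (0.37) among them. Of 16 serine, methionine and folate metabolism genes 6 rose (7 higher adjusted over the list alone, median 0.08, adjusted p = 0.164 by estimated correlation).

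In HSD-fed F1 females, 428 of 10377 genes passed (315 higher and 113 lower). Replicate 1 of the HSD-ancestry group held more male-limited transcripts, 0.73 above the lowest array of the set. In F1 HSD-fed females, leaving out 1 array gave 199 to 420 genes, with shifts over 1.5 times without CD-ancestry replicates 1 (212), 2 (199) and 3 (241), HSD-ancestry replicates 1 (256) and 3 (203). The count was 696 with the 50th percentile dim filter, 793 with a trended robust variance prior and 256 with the arrays holding opposite-sex transcripts left out. With replicate number as a block, where 2 replicate numbers correlated between the groups, it was lower and is given below.

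In F2 the same comparisons were made in the grandchildren of the F0 males. Among CD-fed F2 males, 3 one-carbon genes rose with HSD ancestry: Nmdmc from 11.32 ± 0.11 to 12.05 ± 0.08, a log2 change of 0.74 (SE 0.07, adjusted p = 8.31e-04), CG3999 by 0.41 (SE 0.07) and Shmt, the serine hydroxymethyltransferase gene, by 0.27 (SE 0.06). The purine synthesis gene Gart rose by 0.66 (SE 0.08, adjusted p = 0.00293) and the adenosine deaminase-related gene Adgf-D by 0.59 (SE 0.08). Jon99Fi and sug fell, with log2 changes of -0.87 (SE 0.18, adjusted p = 0.0358) and -0.83 (SE 0.12, adjusted p = 0.0109). fy (1.14), a planar polarity gene, CG15263 (0.90) and the dopamine and ecdysteroid receptor gene DopEcR (0.83) were the largest rises above the filter level, and jeb (1.03) lay near it.

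Of 16 serine, methionine and folate metabolism genes 3 rose (11 higher adjusted over the list alone, median 0.24, adjusted p = 0.404 by estimated correlation). Of 15 purine and urate metabolism genes 2 rose (6 higher adjusted over the list alone, median 0.12, adjusted p = 0.549 by estimated correlation). Of 28 midgut serine protease and lysozyme genes 5 fell (6 lower adjusted over the list alone, median -0.09, adjusted p = 0.549 by estimated correlation), with epsilonTry (-0.41) and Jon65Aii (-0.42) falling. Of 36 testis genes 2 fell (5 lower adjusted over the list alone, median -0.03, -0.09 after quantile normalization, adjusted p = 0.404 by estimated correlation), namely dj (-0.60) and ProtB (-0.28). Of 30 accessory gland and seminal fluid genes 1 fell and 0 rose (4 lower and 1 higher adjusted over the list alone, median -0.09, adjusted p = 0.706 by estimated correlation), with a median of -0.13 after quantile normalization. Of 22 antimicrobial and Bomanin peptide genes 1 fell and 1 rose (4 lower and 1 higher adjusted over the list alone, median -0.08, -0.12 after quantile normalization, adjusted p = 0.706 by estimated correlation), where Def rose (0.48) and Drsl2 fell (-0.34). In CD-fed F2 males, 327 of 10941 genes passed (234 higher and 93 lower). After quantile normalization the split was 155 higher and 165 lower. In F2 CD-fed males, leaving out 1 array gave 21 to 467 genes, with shifts over 1.5 times without CD-ancestry replicates 1 (101) and 3 (80), HSD-ancestry replicates 1 (88), 2 (27), 3 (21) and 4 (129). The count was 1956 with 1 fit of all 80 arrays, 528 with array weights and 538 with a trended robust variance prior.

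In HSD-fed F2 males transcripts of the female germ line and of egg production were among those that rose with HSD ancestry. dhd, the maternal thioredoxin gene deadhead, rose from 5.28 ± 0.09 to 9.03 ± 0.64, a log2 change of 3.75 (SE 0.26, adjusted p = 6.00e-04), and the cyclin gene CycB by 2.42 (SE 0.23, adjusted p = 0.00396). osk, the germ plasm gene oskar, rose by 2.43 (SE 0.36) and zpg, a germ line gap junction gene, by 0.79, both from CD-ancestry means near the lower limit of detection. The yolk protein genes Yp1 (1.78), Yp2 (1.76) and Yp3 (1.48) and the vitelline membrane genes Vm26Aa (1.21) and Vm34Ca (0.95) rose too. CG8329, a predicted serine protease gene, was the 1 gene that fell, with a log2 change of -0.57 (SE 0.06, adjusted p = 0.00681).

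Of 5 yolk protein genes 4 rose (4 higher adjusted over the list alone, median 1.48, adjusted p = 0.0683 by estimated correlation). Of 13 eggshell genes 2 rose (9 higher adjusted over the list alone, median 0.49, adjusted p = 0.103 by estimated correlation). Of 16 ovary germline genes 2 rose (7 higher adjusted over the list alone, median 0.20, adjusted p = 0.102 by estimated correlation). Of 22 DNA replication and cell cycle genes 1 rose (8 higher adjusted over the list alone, median 0.27, adjusted p = 0.346 by estimated correlation). The mean of female-limited transcripts moved with these groups: it was 5.03 ± 0.22 with HSD ancestry and 4.40 ± 0.01 with CD ancestry, and 3 of the 4 HSD-ancestry arrays exceeded the 0.5 mark. HSD-ancestry replicate 2 also stood apart over all genes, with a root mean square deviation from its group of 0.21 (0.11 in each of the other 3) and 0.9918 as its highest r with another array, the lowest of the 80. In HSD-fed F2 males, 22 of 10949 genes passed (21 higher and 1 lower). In F2 HSD-fed males, leaving out 1 array gave 8 to 31 genes, with shifts over 1.5 times without CD-ancestry replicates 1 (11), 2 (10), 3 (8) and 4 (11), HSD-ancestry replicates 1 (12) and 4 (12). The count was 12 with the 50th percentile dim filter, 320 with 1 fit of all 80 arrays, 90 with array weights and 1 with genes limited to the other sex left out.

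**Figure D3:**
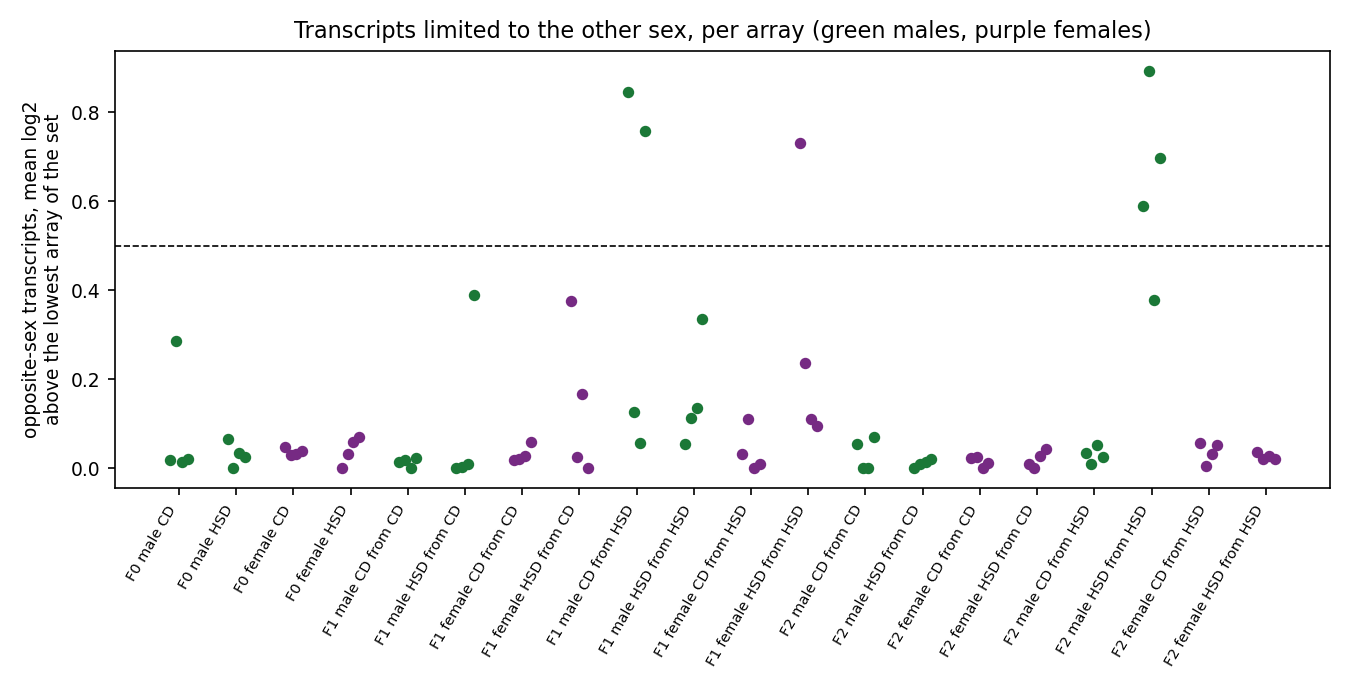
Each point is an array (green males, purple females), and the vertical axis gives the mean log2 value of transcripts limited to the other sex above the lowest array of its set, by group. The dashed mark lies at 0.5, and 6 arrays of HSD ancestry lie over it.

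In CD-fed F2 females the chorion gene Cp7Fc fell from 9.57 ± 0.28 to 8.32 ± 0.21 with HSD ancestry, a log2 change of -1.25 (SE 0.14, adjusted p = 0.00256), and the chorion gene Cp16 had a change of -1.21 (SE 0.22, adjusted p = 0.0266). The follicle cell gene Fcp3C had a log2 change of -1.48 (SE 0.27, adjusted p = 0.0233), and dec, a gene of eggshell assembly, fell from 11.26 ± 0.21 to 10.13 ± 0.19, a log2 change of -1.13 (SE 0.11, adjusted p = 0.00178). Acbp6, an acyl-CoA binding protein gene, rose from 7.25 ± 0.18 to 8.24 ± 0.24, a log2 change of 0.99 (SE 0.12, adjusted p = 0.00454), and the metallothionein gene MtnB by 0.73 (SE 0.11, adjusted p = 0.00954). CG14499 (0.78), lncRNA:CR32368 (0.80) and CG31468 (0.73) rose as well, and CG13114 (-1.20) fell.

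Of 18 eggshell genes 13 fell (18 lower adjusted over the list alone, median -1.05, adjusted p = 0.213 by estimated correlation). Of 21 antimicrobial and Bomanin peptide genes 0 rose (7 higher adjusted over the list alone, median 0.25, adjusted p = 0.495 by estimated correlation). Of 37 odorant-binding protein genes 1 fell and 0 rose (1 lower and 2 higher adjusted over the list alone, median 0.09, adjusted p = 0.300 by estimated correlation), and the gene that fell was Obp19c (-0.87). In CD-fed F2 females, 132 of 10211 genes passed (51 higher and 81 lower). After quantile normalization the split was 80 higher and 70 lower. In F2 CD-fed females, leaving out 1 array gave 53 to 468 genes, with shifts over 1.5 times without CD-ancestry replicates 2 (468), 3 (59) and 4 (70), HSD-ancestry replicates 1 (64), 2 (209), 3 (64) and 4 (53). The count was 226 with the 50th percentile dim filter, 1333 with 1 fit of all 80 arrays, 1059 with array weights and 307 with a trended robust variance prior.

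In HSD-fed F2 females the antimicrobial peptide gene Mtk rose from 9.52 ± 0.21 to 10.26 ± 0.14 with HSD ancestry, a log2 change of 0.73 (SE 0.11, adjusted p = 0.0219), and the immune peptide gene BomT2 by 0.58 (SE 0.09, adjusted p = 0.0219). PGRP-SB1 rose by 0.53 (SE 0.07), the antiviral gene Vago by 0.79 (SE 0.12) and Acbp6 by 0.73 (SE 0.09). The eggshell genes yellow-g2 (-0.97) and Cp36 (-0.61) fell, beside the ecdysone synthesis gene nvd (-0.62), the flight muscle actin gene Act88F (-0.61) and CG4009 (-0.79). The lysozyme gene LysX rose (0.78), while Jon65Ai (-0.40) and Jon65Aii (-0.44) fell.

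Of 21 antimicrobial and Bomanin peptide genes 0 fell and 3 rose (1 lower and 10 higher adjusted over the list alone, median 0.14, adjusted p = 0.403 by estimated correlation). Of 29 midgut serine protease and lysozyme genes 5 fell and 1 rose (17 lower and 1 higher adjusted over the list alone, median -0.15, adjusted p = 0.415 by estimated correlation). Of 18 eggshell genes 2 fell (9 lower adjusted over the list alone, median -0.27, adjusted p = 0.416 by estimated correlation). Of 21 immune recognition and signalling genes 1 rose (1 higher adjusted over the list alone, median 0.06, 0.09 after quantile normalization, adjusted p = 0.403 by estimated correlation). In HSD-fed F2 females, 82 of 10393 genes passed (42 higher and 40 lower). After quantile normalization the split was 90 higher and 41 lower. In F2 HSD-fed females, leaving out 1 array gave 15 to 103 genes, and the count moved by over 1.5 times without CD-ancestry replicates 1 (37), 2 (22), 3 (19) and 4 (15), HSD-ancestry replicates 3 (23) and 4 (32). The count was 231 with the 50th percentile dim filter, 131 with quantile normalization, 245 with 1 fit of all 80 arrays, 191 with array weights and 312 with a trended robust variance prior. With replicate number as a block, which did not pair the samples, it was far lower and is given below.

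**Figure D4:**
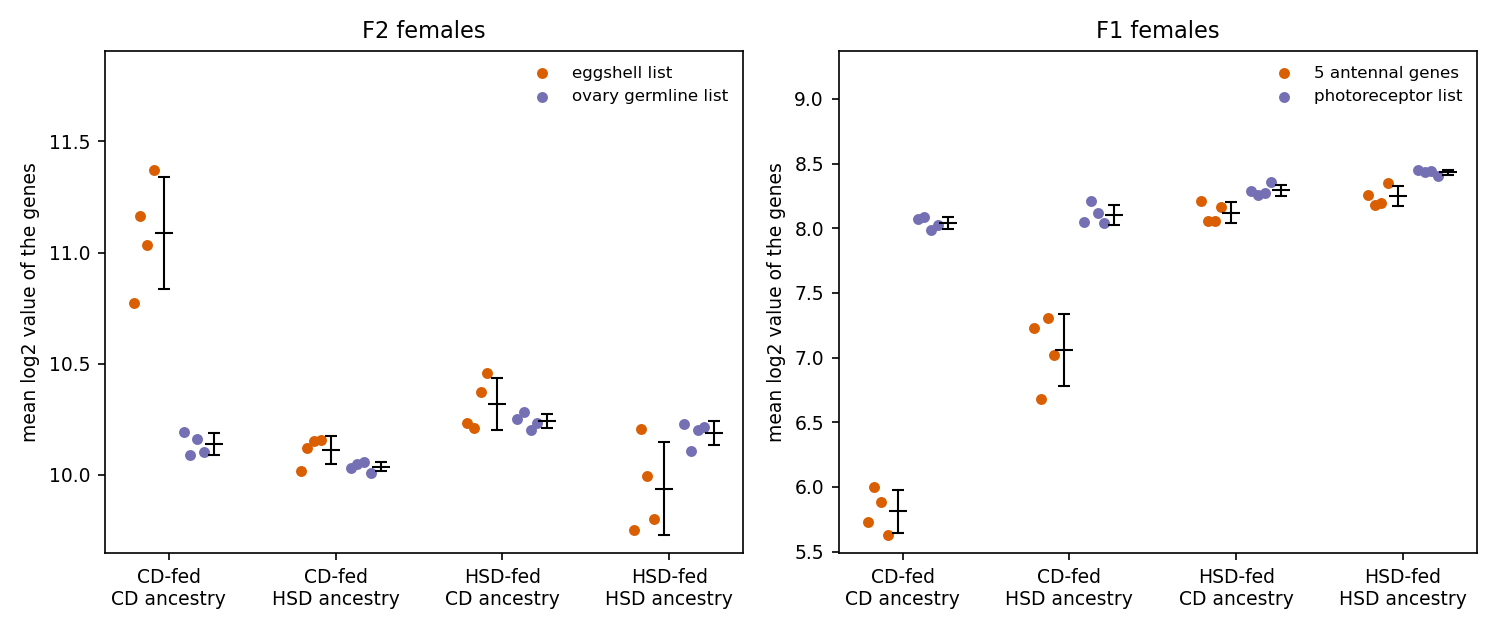
Points are arrays and bars are means ± SD (n = 4) of the mean log2 value of the eggshell and ovary germline lists in F2 females (left) and of Obp19a, Obp83b, Os-C, Obp69a and a10, chosen after their values were seen, and the photoreceptor list in F1 females (right). In CD-fed F1 females the 5 genes averaged 5.81 with CD ancestry and 7.06 with HSD ancestry, while CD-fed and HSD-fed groups belong to different batches.

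The mean change with ancestry over both diets was fitted on 8 arrays against 8 with own diet, and so batch, as a term. Such a mean can come mostly from 1 diet. By the within-diet changes above, it did for Obp19a, dhd, Hsp68, Obp83b, CG3819, yellow-g, Yp2, dj and sug. In F1 females Hsp68 fell by this measure (-0.68, SE 0.08), and Obp83b (0.85, SE 0.10), Obp19a (0.83, SE 0.10) and CG9733 (0.82, SE 0.10) rose. Of 38 odorant-binding protein genes 0 fell and 13 rose (1 lower and 17 higher adjusted over the list alone, median 0.15, adjusted p = 0.0311 by estimated correlation). Of 10 heat shock and chaperone genes 2 fell (6 lower adjusted over the list alone, median -0.09, adjusted p = 0.0311 by estimated correlation). In F2 females the eggshell genes yellow-g2 (-1.02, SE 0.14) and Cp7Fc (-0.93, SE 0.10) fell, and Acbp6 (0.86, SE 0.08) and LysX (0.59, SE 0.13) rose. Of 18 eggshell genes 17 fell (18 lower adjusted over the list alone, median -0.71, adjusted p = 0.164 by estimated correlation). Of 21 antimicrobial and Bomanin peptide genes 6 rose (9 higher adjusted over the list alone, median 0.20, adjusted p = 0.224 by estimated correlation). In F1 males CG3819 (0.55, SE 0.06) and AANATL3 (0.42, SE 0.04) rose, and yellow-g (-0.30, SE 0.06) fell. In F2 males dhd (1.83, SE 0.19) and Yp2 (0.90, SE 0.11) rose, and dj (-0.33, SE 0.05) and sug (-0.38, SE 0.09) fell.

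Averaged in F1 males, 567 of 11137 genes passed (401 higher and 166 lower). Over F1 males, leaving out 1 array gave 272 to 815 genes, with shifts over 1.5 times without CD-fed CD-ancestry replicate 3 (333), HSD-fed CD-ancestry replicates 1 (287) and 2 (350), CD-fed HSD-ancestry replicates 1 (346) and 4 (363), HSD-fed HSD-ancestry replicates 2 (316), 3 (327) and 4 (272). F1 males had counts of 305 with 1 fit of all 80 arrays, 0 without the batch term (limma, 134 at an unadjusted p under 0.05) and 193 with the arrays holding opposite-sex transcripts left out. Averaged in F1 females, 784 of 10675 genes passed (639 higher and 145 lower, and 512 higher and 252 lower after quantile normalization). Over F1 females, leaving out 1 array gave 521 to 1061 genes, with shifts over 1.5 times without HSD-fed HSD-ancestry replicate 3 (521). F1 females had counts of 1262 with array weights and 0 without the batch term (limma, 242 at an unadjusted p under 0.05). Averaged in F2 males, 131 of 11161 genes passed (108 higher and 23 lower, and 80 higher and 49 lower after quantile normalization). Over F2 males, leaving out 1 array gave 60 to 246 genes, with shifts over 1.5 times without CD-fed CD-ancestry replicates 3 (82) and 4 (246), HSD-fed CD-ancestry replicates 1 (84), 2 (60) and 4 (67), CD-fed HSD-ancestry replicates 2 (63) and 3 (61), HSD-fed HSD-ancestry replicate 1 (82). F2 males had counts of 202 with the 50th percentile dim filter, 1616 with 1 fit of all 80 arrays, 413 with array weights, 232 with a trended robust variance prior, 0 without the batch term (limma, 331 at an unadjusted p under 0.05) and 63 with genes limited to the other sex left out. Averaged in F2 females, 1080 of 10676 genes passed (259 higher and 821 lower, and 425 higher and 344 lower after quantile normalization). Over F2 females, leaving out 1 array gave 473 to 2043 genes, with shifts over 1.5 times without CD-fed CD-ancestry replicates 2 (2043), 3 (558) and 4 (573), HSD-fed CD-ancestry replicates 2 (625), 3 (557) and 4 (536), CD-fed HSD-ancestry replicates 1 (491) and 4 (473), HSD-fed HSD-ancestry replicate 3 (555). F2 females had counts of 2278 with array weights and 9 without the batch term.

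The difference, HSD-fed minus CD-fed ancestry change, was tested, but cannot tell diet from batch, each diet being its own batch. In F1 males the difference was -1.04 (SE 0.09) for phu and -3.08 (SE 0.80) for TotC, and 0.73 (SE 0.13) for Acsx1L and 0.70 (SE 0.11) for CG8112. In F1 females it was -1.40 (SE 0.17) for NimC4 and -1.48 (SE 0.21) for Obp19a, and 0.85 (SE 0.10) for MtnC and 1.10 (SE 0.17) for CG16898. In F2 males it was -1.25 (SE 0.16) for fy and -1.05 (SE 0.12) for CG8329, and 3.84 (SE 0.37) for dhd and 1.87 (SE 0.21) for Yp1. In F2 females it was -0.80 (SE 0.15) for Jon99Ci and -0.77 (SE 0.14) for the trypsin gene Try29F, and 0.87 (SE 0.15) for dec and 0.67 (SE 0.12) for Cyp4p1.

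The difference passed for 420 of 11137 genes in F1 males (108 higher and 312 lower in HSD-fed flies). For F1 males the range with 1 array left out was 179 to 603 genes, with shifts over 1.5 times without CD-fed CD-ancestry replicates 1 (235) and 3 (253), HSD-fed CD-ancestry replicates 1 (253), 3 (268) and 4 (201), CD-fed HSD-ancestry replicates 1 (233) and 4 (227), HSD-fed HSD-ancestry replicates 1 (179) and 4 (207). The F1 males comparison gave 158 with 1 fit of all 80 arrays, 678 with a trended robust variance prior and 136 with the arrays holding opposite-sex transcripts left out. The difference passed for 305 of 10675 genes in F1 females (77 higher and 228 lower in HSD-fed flies). The F1 females comparison gave 517 with array weights. The difference passed for 103 of 11161 genes in F2 males (58 higher and 45 lower in HSD-fed flies, and 95 higher and 42 lower after quantile normalization). For F2 males the range with 1 array left out was 65 to 148 genes, with shifts over 1.5 times without HSD-fed CD-ancestry replicates 1 (67), 2 (67) and 3 (65). The F2 males comparison gave 850 with 1 fit of all 80 arrays and 383 with array weights. The difference passed for 18 of 10676 genes in F2 females (11 higher and 7 lower in HSD-fed flies). For F2 females the range with 1 array left out was 0 to 50 genes, with shifts over 1.5 times without CD-fed CD-ancestry replicates 1 (50), 2 (46), 3 (11) and 4 (11), HSD-fed CD-ancestry replicates 1 (1), 2 (11), 3 (0) and 4 (11), CD-fed HSD-ancestry replicates 2 (28), 3 (0) and 4 (0), HSD-fed HSD-ancestry replicates 1 (36) and 3 (0), and with limma 932 to 1116 genes had an unadjusted p under 0.05 where the count was 0. The F2 females comparison gave 30 with quantile normalization, 141 with 1 fit of all 80 arrays, 92 with array weights and 61 with a trended robust variance prior.

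Some genes passed in several of the 8 ancestry comparisons with the same sign. Of 1419 genes that passed in at least 1, 275 passed in at least 2, of which 191 had 1 sign and 84 opposite signs, and 24 passed in at least 3 with 1 sign. Cht4 passed in F1 CD-fed females (0.25), F1 HSD-fed females (0.62), F2 CD-fed females (0.43) and F2 HSD-fed females (0.61), each time higher, and it encodes a chitinase. CG9459 passed in F1 CD-fed males (0.45), F1 CD-fed females (0.41), F1 HSD-fed females (0.40) and F2 CD-fed females (0.25), a fatty acid elongase-like gene. CG13482 passed in F1 CD-fed females (0.40), F2 CD-fed males (0.41), F2 CD-fed females (0.73) and F2 HSD-fed females (0.43). Acbp6 passed in F1 HSD-fed females (0.52), F2 CD-fed females (0.99) and F2 HSD-fed females (0.73). mesh passed in F1 HSD-fed females (0.24), F2 CD-fed females (0.33) and F2 HSD-fed females (0.50), and it encodes a septate junction protein of the midgut. Mal-B1 passed in F1 HSD-fed females (0.40), F2 CD-fed males (0.73) and F2 CD-fed females (0.62). hdly passed in F1 HSD-fed females (0.47), F2 CD-fed males (0.29) and F2 HSD-fed females (0.59). CG15043 passed in F1 CD-fed males (0.36), F1 CD-fed females (0.50) and F2 HSD-fed females (0.44), and CG17562 passed in F1 CD-fed males (0.43), F1 CD-fed females (0.39) and F1 HSD-fed females (0.32). Jon65Aii passed in 3 comparisons as lower, with F2 CD-fed males at -0.42, F2 CD-fed females at -0.75 and F2 HSD-fed females at -0.44.

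Overlaps of these calls were counted with the number that independent lists would share, without a test. CD-fed F1 males and females had 50 genes higher in both, where independent lists would share 8.91. CD-fed and HSD-fed F1 females had 40 genes higher in both, where independent lists would share 8.0. HSD-fed F1 females and CD-fed F2 males had 33 genes higher in both, where independent lists would share 7.18. CD-fed and HSD-fed F2 females had 11 genes lower in both, where independent lists would share 0.310, the group that includes eggshell genes. Opposite signs exceeded such numbers as well: 14 genes for F1 CD-fed males and F2 CD-fed females (3.03), 13 genes for F1 CD-fed females and F2 CD-fed males (2.29), 11 genes for F1 CD-fed males and F2 HSD-fed females (1.62) and 11 genes for F1 CD-fed females and F2 CD-fed females (2.15).

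Log2 changes were correlated across genes between each pair of the 10 within-batch comparisons, 45 relations in all. Genes are not independent replicates, so p is a permutation p, the share of 1225 combinations of regrouped arrays with as large an absolute r. Between F0 males and F0 females Pearson r was 0.575 (p = 8.16e-04, the smallest the regroupings can give, adjusted p = 0.0122) and Spearman rho 0.345 (p = 0.00163, adjusted p = 0.0735). Between HSD-fed F1 males and females r was 0.238 (p = 8.16e-04, adjusted p = 0.0122) and rho 0.197 (p = 0.0188, adjusted p = 0.280). Between CD-fed and HSD-fed F2 females r was 0.408 (p = 8.16e-04, adjusted p = 0.0122) and rho 0.353 (p = 0.00735, adjusted p = 0.165). The other 42 relations did not pass, 0 passed by rho, and with the 50th percentile dim filter 2 passed by r. Between the F0 male diet change and the ancestry change of CD-fed F2 males r was -0.246 (p = 0.0147, adjusted p = 0.165), and rho -0.205 (p = 0.0384, adjusted p = 0.280).

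**Figure D5:**
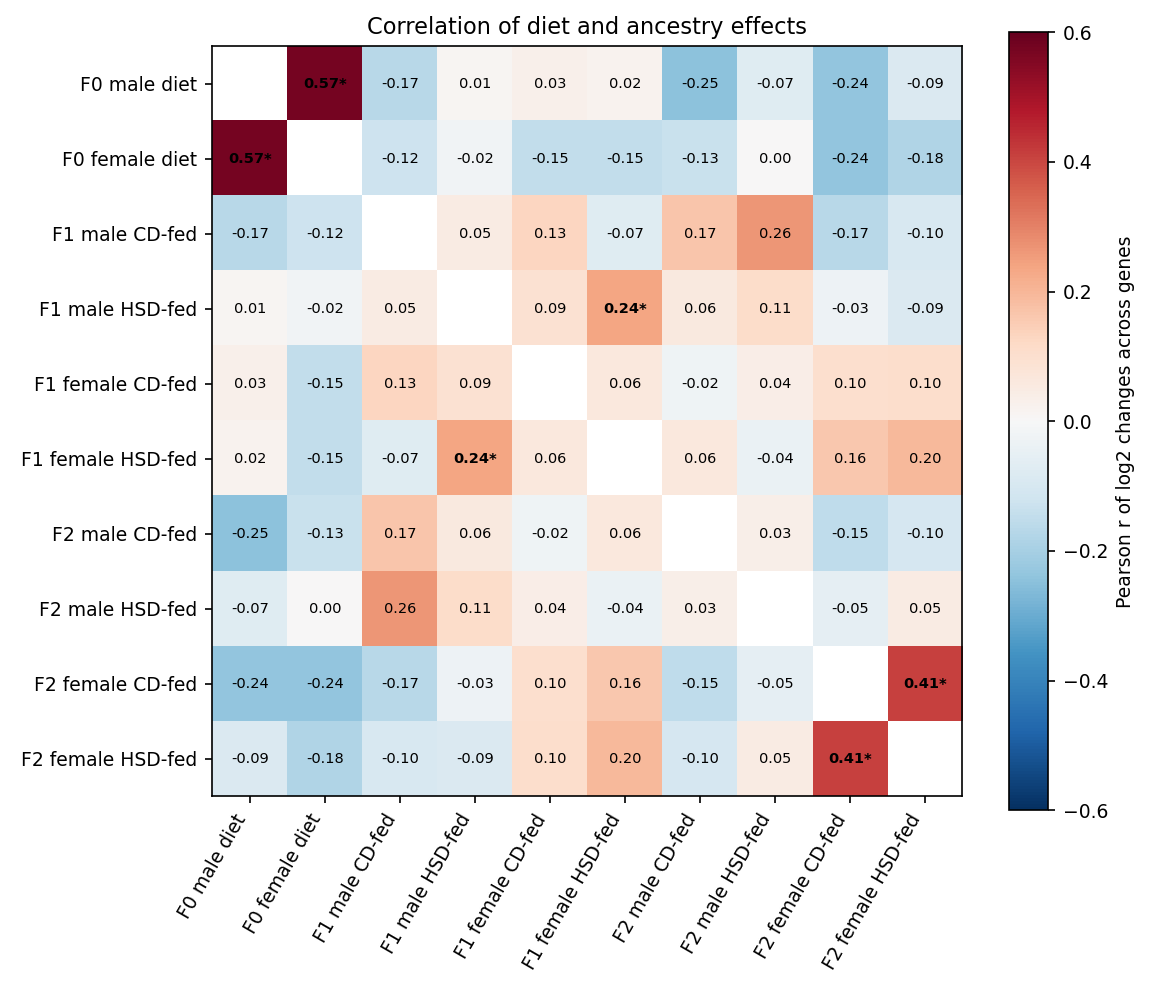
Each cell gives Pearson r across genes between the log2 changes of a pair of the 10 within-batch comparisons, colored from blue (negative) to red (positive), with an asterisk where the adjusted permutation p passed. The 3 marked relations have r of 0.575, 0.238 and 0.408.

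In F1 and F2 each own diet was a batch of its own, normalized as a separate set, so own diet and batch cannot be told apart, and no fit with batch as a term could be had. HSD-fed minus CD-fed values passed for 10163 of 11137 genes in F1 males and 9508 of 10675 in F1 females, with the median of all genes at 0.46 and 0.41. In F2 they passed for 9453 of 11161 genes in males and 9161 of 10676 in females, with medians of -0.38 and -0.14. These counts split into 8295 higher and 1868 lower, 7559 and 1949, 1309 and 8144, and 3540 and 5621, in the same order. Quantile normalization shifted those medians by -0.46, -0.39, 0.37 and 0.15, and gave 4798 higher and 4725 lower, 4711 and 4386, 4051 and 4342, and 4461 and 4295. Relative to the medians of the genes shared with F0 (0.47, 0.42, -0.38 and -0.13), genes changed at least 1.5-fold in F0 kept their sign in 206 of 255 for F1 males, 611 of 686 for F1 females, 216 of 254 for F2 males and 585 of 686 for F2 females. Pearson r with the F0 change of the same sex, across genes, which are not independent replicates, was 0.125 in F1 males, 0.525 in F1 females, 0.209 in F2 males and 0.522 in F2 females, with rho of -0.055, 0.456, 0.020 and 0.479 and no p, since batch moves with diet.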

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

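Of the tests of explanations in this part, only that on antennal tissue was chosen before its result was seen, while the tests of differences between diets and sexes were planned. Yolk and maternal transcripts were higher in HSD-fed F2 males of HSD ancestry, and female-limited genes as a set moved with them: their median log2 change was 0.57 (95% range over resampled genes 0.45 to 0.85, 60 genes), and 98.3% of them were higher. The dim filter admits a gene that is bright enough in either group, which favors rises here, and without it the median of all 78 was 0.43 (0.32 to 0.56), with 96.2% higher. A single array does not account for it, since the median was 0.49 (0.34 to 0.69) without HSD-ancestry replicate 2 (0.34 unfiltered), nor does an ancestry effect common to both diets: in CD-fed F2 males the genes measured there had a median of -0.0205 (-0.06 to 0.04, 39 genes), where at least 0.28 was required, and of -0.0040 unfiltered. RNA of females in these male samples is a candidate source consistent with the set median, and would be a median share of 0.483% (interquartile range 0.376 to 0.679), or 0.437% unfiltered. Such shares divide by levels in HSD-fed F2 females, a separately normalized set, so their size is approximate. The share implied by dhd (3.39%), Yp1 (3.33%) and CycB (2.17%) was larger, and saturation of the brightest probe sets as a reason was not tested. An effect of ancestry on these genes in HSD-fed males alone stays open, since the differences between diets for dhd and Yp1 would follow from either.

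Eggshell genes were lower in CD-fed F2 females of HSD ancestry, with a median log2 change of -1.05 over 18 genes. A smaller share of ovary RNA does not account for its size, since the ovary germline list had a median of -0.12 (-0.15 to -0.05, 17 genes). Nor does a single array, since the median nearest 0 was -0.92, without CD-ancestry replicate 4, and after quantile normalization it was -1.0. A smaller number of late-stage egg chambers, in which these genes are active, may account for it and was not tested; ancestry, which the design names, stays open as well.

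Obp19a, Obp83b, Os-C, Obp69a and a10, antennal genes grouped after their values were seen, had a median log2 change of 1.47 in CD-fed F1 females of HSD ancestry, although a second probe set of Obp19a changed by 0.48. More head tissue does not account for it, since the photoreceptor list had a median of 0.0575 (-0.01 to 0.11, 18 genes), nor does a single array, since the median nearest 0 was 1.36, without CD-ancestry replicate 4. More antennal tissue is not excluded: 11 other antennal genes had a median of 0.18 (0.06 to 0.49), under the bound of 0.5 times the median of the 5 that was set in advance against it, but 8 of them, lush (0.54) and a5 (0.75) included, lay within 1 log2 unit of the filter level of 4.23, a limit added after the value was seen. The 3 clear of it, Obp28a (0.49), Ir25a (0.20) and Snmp1 (-0.18), lay under that bound too and count against it, while what other tissues add to their signal was not measured; more antennal tissue and regulation by ancestry cannot be told apart.

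In 20 of 522 sets of a named gene and a group, 1 of the 4 arrays lay apart, with a gap of over 0.829 of the range, and chance gives about 1 in 20 of such sets. Values are log2, each with the mean of the other 3 arrays in parentheses. These were Act88F at 8.0 (7.37) in CD F0 females, replicate 4, brm at 10.24 (10.35), Mlp60A at 11.57 (11.47) and Orc1 at 9.54 (9.76) in CD F0 females, replicate 2, and CG12374 at 13.37 (13.57) and Jon65Ai at 9.94 (10.46) in HSD F0 females, replicate 1. Further sets were CG31468 at 12.67 (12.47) and Sardh at 8.13 (7.64) in CD F0 males, replicate 1, Mal-A4 at 9.90 (10.08) in HSD F0 males, replicate 3, and CG16898 at 9.29 (9.54) in CD-fed F1 females of CD ancestry, replicate 3. Other genes were CG9733 at 5.73 (5.36) in CD-fed F1 females of CD ancestry, replicate 2, CG17562 at 8.93 (8.55) in CD-fed F1 females of HSD ancestry, replicate 2, and CG9701 at 9.04 (8.71) in HSD-fed F1 females of CD ancestry, replicate 4. Others apart were Cyp309a1 at 8.28 (8.56) and Obp19a at 8.04 (7.77) in HSD-fed F1 females of HSD ancestry, replicate 4, VAChT at 6.79 (6.69) in CD-fed F1 males of HSD ancestry, replicate 2, and MtnB at 9.59 (9.12) in CD-fed F2 females of CD ancestry, replicate 2. The next were Jon65Ai at 9.30 (9.51) in HSD-fed F2 females of CD ancestry, replicate 1, Def at 9.48 (9.86) in CD-fed F2 males of CD ancestry, replicate 2, and dhd at 6.93 (5.73) in CD-fed F2 males of CD ancestry, replicate 4. The mean of transcripts limited to the other sex lay apart in 2 of 40 sets of an array measure and a group, at 4.48 in CD F0 males, replicate 2 (4.21) and 5.47 in HSD-fed F1 males of CD ancestry, replicate 4 (5.09).

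Some changes passed a test of the difference between diets (each a batch) or sexes. For F1 males the ancestry change differed between diets (HSD-fed minus CD-fed) in 420 genes, among them Acsx1L (0.73, adjusted p = 0.00711), CG8112 (0.70, adjusted p = 0.00366), TotC (-3.08, adjusted p = 0.0428) and phu (-1.04, adjusted p = 2.49e-05). For F1 females it did in 305 genes, among them CG16898 (1.10, adjusted p = 0.00346), MtnC (0.85, adjusted p = 5.40e-04), NimC4 (-1.40, adjusted p = 5.41e-04) and Obp19a (-1.48, adjusted p = 0.00125). For F2 males it did in 103 genes, among them CG8329 (-1.05, adjusted p = 2.23e-04), Yp1 (1.87, adjusted p = 1.81e-04), dhd (3.84, adjusted p = 8.29e-05) and fy (-1.25, adjusted p = 5.57e-04). For F2 females it did in 18 genes, among them Cyp4p1 (0.67, adjusted p = 0.0266), Jon99Ci (-0.80, adjusted p = 0.0379), Try29F (-0.77, adjusted p = 0.0333) and dec (0.87, adjusted p = 0.0266). For F0 flies the diet change differed between sexes (female minus male) in 3445 genes, among them CG31468 (-4.16, adjusted p = 2.07e-11), CG34040 (-4.58, adjusted p = 5.31e-08), Jon66Ci (3.65, adjusted p = 2.10e-08) and Jon99Fi (5.12, adjusted p = 2.49e-08). Of probe sets without a single gene symbol, which no comparison used, 306 of 1893 passed with diet in F0 males and 466 of 1969 in F0 females.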

How the results depend on the processing

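The alternatives on opposite-sex transcripts were chosen after the results were seen, and the others were set in advance. Of 264 named genes in their comparisons, 163 kept their direction and side of the threshold in every alternative tried other than leaving out arrays; over 2456 such values, 2296 were kept, 153 lost the threshold and 7 passed only there. With 1 array left out, 2018 of 2392 values were kept and 372 lost the threshold with fewer samples. Only Pepck1 in F0 females, which did not pass, turned direction: with 1 array left out its log2 change ran from -0.11 to 0.0147, the latter without HSD replicate 4. The counts that moved by over 1.5 times were as follows, and the cause was not tested unless given. With 1 fit of all 80 arrays the counts were F1 CD-fed males 932, F1 HSD-fed males 33, F1 CD-fed females 663, F2 CD-fed males 1956, F2 HSD-fed males 320, F2 CD-fed females 1333, F2 HSD-fed females 245, F1 males averaged 305, F2 males averaged 1616, F1 males by diet 158, F2 males by diet 850 and F2 females by diet 141. With array weights the counts were F1 CD-fed males 894, F1 CD-fed females 497, F2 CD-fed males 528, F2 HSD-fed males 90, F2 CD-fed females 1059, F2 HSD-fed females 191, F1 females averaged 1262, F2 males averaged 413, F2 females averaged 2278, F1 females by diet 517, F2 males by diet 383 and F2 females by diet 92. With the dim filter at the 50th percentile, which tests fewer genes, the counts were F1 CD-fed males 955, F1 HSD-fed males 21, F1 HSD-fed females 696, F2 HSD-fed males 12, F2 CD-fed females 226, F2 HSD-fed females 231 and F2 males averaged 202. After quantile normalization the counts were F1 CD-fed males 852, F2 HSD-fed females 131 and F2 females by diet 30. With a trended robust variance prior the counts were F1 CD-fed males 1213, F1 HSD-fed males 100, F1 CD-fed females 442, F1 HSD-fed females 793, F2 CD-fed males 538, F2 CD-fed females 307, F2 HSD-fed females 312, F2 males averaged 232, F1 males by diet 678 and F2 females by diet 61. Without the 6 arrays over the opposite-sex mark, which leaves fewer arrays, the counts were F1 CD-fed males 60, F1 HSD-fed females 256, F2 HSD-fed males 5, F1 males averaged 193, F2 males averaged 15, F1 males by diet 136 and F2 males by diet 23. Without genes limited to the other sex the counts were F2 HSD-fed males 1 and F2 males averaged 63. Without the batch term the averaged counts were F1 males 0, F1 females 0, F2 males 0 and F2 females 9 (limma, 134, 242 and 331 at an unadjusted p under 0.05 where 0), as the batch shift then enters the spread. The 110 list calls became 0 with an estimated correlation (limma camera, 38 at an unadjusted p under 0.05), and the 3 correlations of effects became 0 with Spearman in place of Pearson.

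Replicate numbers did not pair the samples: in no comparison were all 4 correlations between same-numbered arrays above 0.1, and in none did every array correlate best with its own number. With replicate number as a block the counts were F1 CD-fed males 279, F1 CD-fed females 155, F1 HSD-fed females 112, F2 CD-fed males 133, F2 HSD-fed females 4, F2 males averaged 54, F2 females averaged 267, F1 males by diet 202, F2 males by diet 56 and F2 females by diet 0 (limma, 913 at an unadjusted p under 0.05 in the last by-diet comparison), and fewer residual degrees of freedom were left.

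With each array left out in turn the counts ranged as follows, and arrays whose removal moved a count by over 1.5 times are named beside each comparison: F0 males 2637 to 3365, F0 females 3658 to 4417, F1 CD-fed males 154 to 566, F1 HSD-fed males 0 to 2, F1 CD-fed females 95 to 222, F1 HSD-fed females 199 to 420, F2 CD-fed males 21 to 467, F2 HSD-fed males 8 to 31, F2 CD-fed females 53 to 468, F2 HSD-fed females 15 to 103, F1 males averaged 272 to 815, F1 females averaged 521 to 1061, F2 males averaged 60 to 246, F2 females averaged 473 to 2043, F1 males by diet 179 to 603, F1 females by diet 206 to 407, F2 males by diet 65 to 148, F2 females by diet 0 to 50, F0 by sex 2983 to 3643, F1 males own diet 10103 to 10157, F1 females own diet 9414 to 9525, F2 males own diet 9301 to 9602 and F2 females own diet 9041 to 9140. Signal over background limits changes in dim genes, since genes under the 25th percentile in every group were not tested, and near that level changes are compressed.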

Other observations

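The tests of other splits below were chosen after the counts were seen, and no other test in this part was. In HSD-fed F0 females, of 20 muscle genes 10 rose (10 higher adjusted over the list alone, median 0.21, adjusted p = 0.741 by estimated correlation), among them Act88F (1.66), bt (0.57) and Mlp60A (0.36), muscle protein genes. In CD-fed F1 males of HSD ancestry, where replicates 1 and 4 held more female-limited transcripts, of 18 photoreceptor genes 4 fell and 1 rose (5 lower and 1 higher adjusted over the list alone, median -0.12, adjusted p = 0.583 by estimated correlation), with rdgB (-0.28) and trp (-0.24) lower and the scavenger receptor gene ninaD (0.60) higher. Of 29 neuron genes 2 fell (5 lower adjusted over the list alone, median -0.11, adjusted p = 0.372 by estimated correlation), namely the acetylcholine transporter gene VAChT (-0.32) and the potassium channel gene Sh (-0.24).

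Further lists were called in HSD-fed F1 females of HSD ancestry. Of 89 detoxification genes 1 fell and 17 rose (4 lower and 28 higher adjusted over the list alone, median 0.07, 0.05 after quantile normalization, adjusted p = 0.205 by estimated correlation), including Cyp309a1 (0.63) and Ugt49C1 (0.37). Of 20 muscle genes 2 rose (5 higher adjusted over the list alone, median 0.08, adjusted p = 0.410 by estimated correlation), the sarcomere genes sls (0.30) and bt (0.19). Of 8 circadian clock genes 1 rose (4 higher adjusted over the list alone, median 0.12, adjusted p = 0.261 by estimated correlation), the clock gene tim (0.27). The odorant-binding protein gene Obp44a (0.41) and the lipase gene Lip2 (0.49) rose as well. Averaged over diets in F2 females, of 25 small RNA pathway genes 6 fell (12 lower adjusted over the list alone, median -0.10, adjusted p = 0.573 by estimated correlation). In the same flies the odorant-binding list, called as higher, had a median of 0.0007 and a mean of -0.0054.

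Tissue, cell cycle and immune peptide lists called in F0 or within a diet and not given elsewhere, none past the threshold with an estimated correlation, had these median log2 changes. They were accessory gland and seminal fluid 0.04 in F1 HSD-fed males, and antimicrobial and Bomanin peptide 0.15 and DNA replication and cell cycle -0.09 in F1 CD-fed females. In F1 HSD-fed females they were antimicrobial and Bomanin peptide -0.08, DNA replication and cell cycle -0.04, eggshell -0.17, ovary germline -0.05, neuron 0.08 and fat body 0.09, and a smaller share of ovary RNA as a reason was not tested. Others were DNA replication and cell cycle -0.09 in F2 CD-fed males, midgut serine protease and lysozyme 0.03 and neuron -0.10 in F2 HSD-fed males, and photoreceptor 0.06 and fat body 0.06 in F2 HSD-fed females. The other lists called there had medians of -0.13 to 0.10, and the 53 called in the averaged comparisons, given only in part, -0.71 to 0.84.

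Other splits of the same arrays were counted, and the mark was under 5% with as many genes. In 35 splits of 8 arrays, 1 split, the real one, gave as many genes in F0 males (3358, 0), F0 females (4239, 1), F1 CD-fed males (488, 1), F1 CD-fed females (271, 0), F1 HSD-fed females (428, 1), F2 CD-fed males (327, 0), F2 HSD-fed males (22, 0), F2 CD-fed females (132, 11) and F2 HSD-fed females (82, 0), where parentheses hold the real and the highest other count. In HSD-fed F1 males the real count was 0, which every split reaches (35 of 35, highest other 1; limma, 1274 genes at an unadjusted p under 0.05), so these splits decide nothing. In 100 splits of 16 arrays, which can keep the real grouping of 1 sex, diet or ancestry, 1 split, the real one, gave as many genes in F1 males averaged (567, 232), F1 females averaged (784, 90), F2 males averaged (131, 20), F2 females averaged (1080, 39), F1 females by diet (305, 196), F2 males by diet (103, 16), F0 by sex (3445, 3232), F1 males own diet (10163, 0), F1 females own diet (9508, 8340), F2 males own diet (9453, 7538) and F2 females own diet (9161, 7838). For F1 males by diet 2 of 100 splits gave as many (420, 423), and for F2 females by diet 3 of 100 (18, 39). With 100 of 2450 possible splits their share may exceed 5%. Splits cannot decide any difference by diet or sex, since they also undo the changes compared, so chance stays open there. In the others except HSD-fed F1 males chance can be excluded, unadjusted over comparisons, only if arrays are independent, which the labels do not say. Own diet splits are also of batch.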
